A study of Saccharomyces cerevisiae with 27 samples.

How the data were processed

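The series holds 27 spotted arrays of the budding yeast Saccharomyces cerevisiae, wild type of the laboratory strain background W303, of a mating type that the series description leaves open here, read in 2 colours. Each array set RNA from cells of one replicative age, counted in generations, against RNA from young control cells, which per the labels were matched to the conditions of the aged sample. There were 7 arrays at 1 generation, where both channels held young cells, 6 at 8 generations, 7 at 12 generations and 7 at 18-20 generations. Per the labels' protocols, the cells were sorted with magnetic beads and kept in log phase, RNA was extracted with glass beads and columns, and the RNA was amplified from a T7 promoter and coupled to dye. By titles and channel labels, the dyes were inverted on 11 of the 27 arrays, 1, 4, 3 and 3 at the ages in order. The description of 8-generation array 3 does not give the inversion that its title and channel labels give. The labels do not say whether arrays of one age came from separate cultures, so p-values measure the spread between arrays, part of which may be technical.

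Per the file headers, each scanner file gives, for every spot, the median intensity and the median local background in red (Cy5) and green (Cy3), neither corrected nor normalized. The deposited files also give the percentage of a spot's pixels above the background plus 2 SD and the percentage of saturated pixels, and a mark for spots that the scanner software or a person set aside. The authors' processed values are deposited in 1 further table, read here as log2 ratios of aged over young cells, with the sign and scale found by setting each column against the scanner values of its array. How the authors normalized and centred that table is not given in the sources used here, and its column medians ran from -0.0625 to 0.0984. It was used only as an alternative. Of its 27 columns, 23 correlated best with their own array. The 8-generation columns 1 and 3 matched each other's scanner file (r = 0.969 and 0.943 over spots) and ran against their own (r = -0.581 and -0.571), and 1-generation columns 3 and 4 each correlated better with the other's scanner file than with their own. Which of the 2 sources holds the right order stays unknown.

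All computation used R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50, the log ratio of each array was normalized by loess with a span of 0.3, and marked spots were left out, between 174 and 1157 of the 6580 spots of an array (median 447). Each log ratio was turned to read aged over young by the dye of the label, so positive values stand for higher levels in aged cells. Spots of one gene were averaged. A gene was tested if it had an unmarked spot on at least 3 arrays of every age, which left 5865 genes. Of the 6388 systematic names on the arrays, 5849 matched a locus tag of the RefSeq gene table (assembly R64 of the reference strain S288C), used for names alone, and the file's name was kept otherwise. Probes that list several genes (322) were tested but not named, except 5 of the mating type cassettes, chosen after the fall of alpha cell genes was seen. Median brightness per array ran from 292 to 4484.5 in red and from 260 to 3927.5 in green, and between 61.76% and 96.12% of spots in red and between 82.92% and 97.08% in green had over 50% of pixels above background plus 2 SD. The number of arrays limits the precision. The median standard error of a log2 change was 0.164, 0.168, 0.155 and 0.155 at the 4 ages in order.

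One linear model was fitted to all 27 arrays, with a mean for each age and a dye term, and moderated by empirical Bayes. Each age was tested against 0, which is the young control on the same array, and the 3 older ages also against the 1-generation arrays. A slope per generation used 1, 8, 12 and 19, the midpoint of 18-20. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The difference of 18-20 minus 12 generations was tested in the same fit. For 46 gene lists, written before the data were examined, camera was run with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of list members are over all genes tested, and were also taken with adjustment over each list alone. Missing values were filled with the fitted values of the model for camera.

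Genes are named by a rule fixed before the data were examined. It took the 10 largest rises and 10 largest falls at 18-20 generations past the threshold with the sign of the mean on at least 6 of the 7 arrays, the 5 largest of each at 12 and at 8 generations (6 of 7, 5 of 6 arrays), the 3 largest of each at 1 generation, and 5 of each for the trend and for every difference from 1 generation. Where none passed, the 3 genes with the lowest p are named. Each list that is described adds up to 4 members with the largest change at 18-20 generations, and 15 genes were fixed by name (SIR2, FOB1, HSP12, HSP26, CTT1, CIT2, PCK1, ICL1, RNR3, CTS1, DSE2, TDH3, ADH1, HTA1 and MFA1). ICL1 and TDH3 had too few unmarked spots to be tested. The text names part of the genes these rules give, chosen with the values in view, and 1 gene and 1 list are not reported here at all.

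The fit was tested on simulated log ratios with a spread for each gene taken from the real arrays. The counts below need not carry over to the real arrays. Some of those were much alike, 8-generation array 1 ran against others of its age, and the spread within an array rose with age. Of 100 genes changed by 1 on the log2 scale, 93, 92 and 98 were recovered at 8, 12 and 18-20 generations, and of 100 changed by 2, 99, 100 and 99. Of unchanged genes, 11 of 5665 were called at 8 generations, 8 of 5665 at 12 and 22 of 5615 at 18-20, and at 1 generation, with no simulated change, 0 of 5865 were called. At 18-20 generations, camera called a list of 50 simulated genes shifted by 0.7 and did not call an unshifted one. The simulated spread was drawn for each gene on its own. The list test therefore does not show how camera behaves on lists whose genes vary together.

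Alternatives changed the background correction, the normalization within and between arrays, the dye term, the arrays in each fit, array weights, the variance prior, the marked spots, a filter on dim probes, the replicate number as a block, the source of values, the correlation in camera and the ages in the slope, and left out each array in turn. Added after seeing the data were a fit with 8-generation array 1 turned, a fit with much alike arrays averaged (r above 0.85), the array set as a block, and 18-20 generations on arrays 5 to 7 or on arrays 1 to 4 only. The array set is inferred from spot brightness. All 6 8-generation arrays and 18-20-generation array 7 form one set and the other 20 arrays the other, with 241 of 6580 spots over 2 log2 units brighter in the smaller set, 107 of them among the 270 spots at one printing position. The sets overlap in the correlation of brightness between arrays, whose lowest value within a set was 0.705 and highest between the sets 0.812.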

Results

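The arrays compared gene expression in yeast mother cells of increasing replicative age, the number of daughters a cell has produced, with young control cells matched to the same conditions. There were 7 arrays of 1-generation cells, which set young cells against young cells and so give the background of the assay, 6 of 8-generation cells, 7 of 12-generation cells and 7 of 18-20-generation cells. Log ratios are given as aged over young. Expression was measured for 5865 genes on every age. The spread of the log2 ratios within an array (SD) had a median of 0.213 at 1 generation, 0.478 at 8 generations, 0.820 at 12 generations and 1.07 at 18-20 generations. Some arrays of one age were much alike. The 18-20-generation arrays 1 to 4 correlated at r = 0.931 to 0.965 over genes and at most at 0.73 with arrays 5 to 7. The 12-generation arrays 4 and 5 correlated at 0.921, and arrays 6 and 7 at 0.856. Genes are not independent replicates, and the labels do not say whether these arrays share RNA. With alike arrays averaged, an alternative chosen after seeing the data, 2088 genes changed at 12 generations and 2922 at 18-20 generations.

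**Figure D1:**
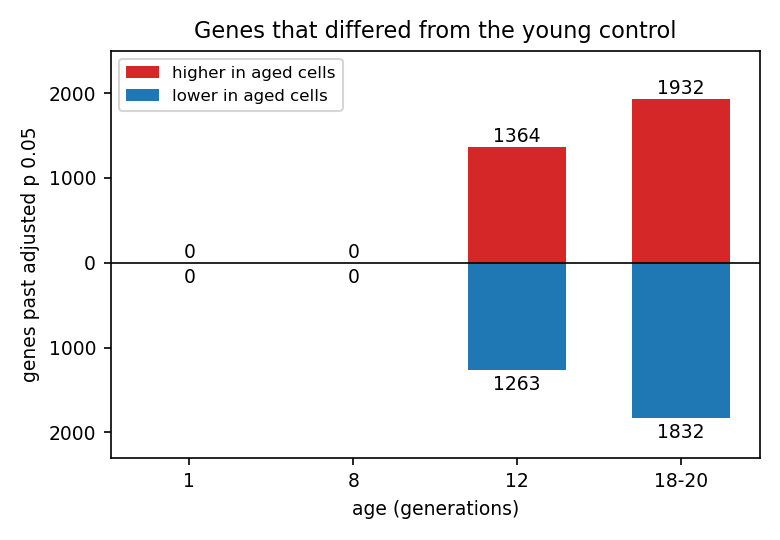
Number of genes past an adjusted p of 0.05 in limma (y axis) at each age in generations (x axis), with genes higher in aged cells above 0 and genes lower below it. No gene passed at 1 or 8 generations, and 1364 rose and 1263 fell at 12 generations against 1932 and 1832 at 18-20 generations.

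At 1 generation, young cells set against young cells showed no gene past the threshold in limma, and 13 of 5865 genes had an unadjusted p under 0.05. That is far below the share of 0.05 that chance alone gives. The fit shares 1 estimate of each gene's spread over all ages, and arrays of this age spread least (median SD 0.213). Their standard errors are therefore too wide (median 0.164, against a median absolute log2 change of 0.0607). The absence of calls is thus largely set by the fit and does not measure how clean the background is. The 3 genes with the lowest p were SND3 (log2 1.32 ± 0.324 SE, n = 5, adjusted p = 1), ORA1 (1.02 ± 0.32, n = 4) and ATP5 (0.83 ± 0.248, n = 4, above background in both channels on 14 of all 27 arrays), with an adjusted p of 1 for each. Of 46 gene lists, 2 passed the preset correlation. Genes of meiosis and sporulation had a median of -0.12 (adjusted p = 7.72e-05) and a cell markers a median of -0.07 (adjusted p = 0.0481), with 0 of 33 and 0 of 7 members past the threshold. Neither held with an estimated correlation (adjusted p = 0.938 and 0.23). The adjusted p of the a cell markers ran from 2.67e-06 to 0.998 over the alternatives. Their median turned to 0.04 when arrays were scaled to each other (adjusted p = 0.998) and to 0.03 without the dye term (adjusted p = 0.974). The call was lost when any of 15 of the 27 arrays was left out, with the highest adjusted p without array 5 (median -0.01, adjusted p = 0.259). The meiosis list did not pass with the array set as a block (adjusted p = 0.48), a fit that moves this age only through 18-20-generation array 7. Arrays 1 and 2, which have opposite dyes, correlated at r = -0.67.

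At 8 generations, no gene passed the threshold in limma, with 748 of 5865 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.0716. The 3 genes with the lowest p were TPK3, a catalytic subunit of protein kinase A (log2 0.76 ± 0.157 SE, n = 6), IBD2, a spindle checkpoint gene (0.64 ± 0.135, n = 6), and ATX2, a Golgi manganese transporter (0.69 ± 0.15, n = 6). With array weights, 755 genes passed. The markers of a cells, genes transcribed in yeast of the a mating type (that of these cells is not settled), had a median of 0.45, and this list passed with the preset correlation (adjusted p = 1.14e-07) and with an estimated one (adjusted p = 0.000198), with 0 of 7 members past the threshold over all genes and 5 adjusted over the list alone. The mean of its array medians was lower, 0.29 ± 0.347 (SD, n = 6, from -0.27 to 0.63). Its probes are dim, above background in both channels on 10 of 27 arrays for STE6, 12 for ASG7, 13 for MFA1, 15 each for AGA2 and BAR1, 17 for MFA2 and 20 for STE2, and the list could not be tested with bright probes alone. MFA1, which encodes the a-factor pheromone, had a log2 value of 0.78 ± 0.183 (adjusted p = 0.0716, n = 4). The other 8 lists that passed with the preset correlation had smaller medians. Mitochondrial ribosome genes had a median of 0.18 (adjusted p = 3.38e-05) and meiosis genes 0.14 (adjusted p = 0.0484). Glycolysis had a median of -0.26 (adjusted p = 0.000624), sulfur and methionine metabolism -0.21 (0.00374), translation factors -0.20 (0.0285), trehalose and glycogen metabolism -0.19 (0.0119), environmental stress response genes -0.14 (0.0484) and heat shock genes -0.12 (0.0285). With an estimated correlation their adjusted p ran from 0.684 for glycolysis to 0.815 for the stress response genes. Of these 8 calls, that of the mitochondrial ribosome held with each array left out in turn, with a median of 0.11 without array 4 (adjusted p = 0.0227). Glycolysis did not pass without array 6 (median -0.18, adjusted p = 0.0711), sulfur metabolism without array 4 (-0.17, 0.11) or 6 (-0.20, 0.051), translation factors without array 2 (-0.15, 0.106) or 5 (-0.14, 0.334), and trehalose and glycogen without array 5 (-0.12, 0.113) or 6 (-0.12, 0.209). Heat shock genes did not pass without array 4 (-0.21, 0.0504) or 6 (-0.22, 0.0958), and their median turned to 0.00418 without array 5 (adjusted p = 0.506). The stress response and meiosis lists did not pass when any of 14 of the 27 arrays was left out, with the highest adjusted p at 0.575 without array 5 (median -0.02) and 0.388 without array 4 (median 0.10). Median centring ended the calls of translation factors, stress response, heat shock and meiosis genes (adjusted p = 0.197, 0.107, 0.103 and 0.552), and the replicate block those of the last 3 (0.148, 0.0603 and 0.0603). Translation factors were lost with print-tip loess (0.0619) and scaling (0.0727) too, and the stress response and meiosis lists without background correction (0.0637 and 0.0602) and under further alternatives. Over all alternatives the adjusted p of these 4 lists began at 0.00185, 1.86e-06, 0.000821 and 0.00203.

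The direction of 8-generation array 1 is not settled. Its label gives the same inverted dyes as arrays 2 and 3, but it correlated with them at r = -0.643 and -0.58 over genes, and with array 4 at -0.661, while arrays 2 and 3 correlated with each other at 0.823. The dyes of array 3 are in doubt too, since its title and channel labels give the inversion and its description does not. Taken as inverted, it correlated with array 4, whose dyes are not inverted, at 0.508. With array 1 turned, 322 genes rose and 210 fell at 8 generations (532 in all), and without it 395 changed. By the same naming rule, the turned fit gave GPG1 (log2 1.24 ± 0.182, adjusted p = 0.000181) and DAD4 (1.32 ± 0.248, adjusted p = 0.00193) among its largest rises, and ERG13, a sterol synthesis gene (-0.93 ± 0.164, adjusted p = 0.00167), and BNA3 (-0.88 ± 0.134, adjusted p = 0.000267) among its largest falls. Gene lists were also tested with array 1 turned. Then a cell markers rose in 4 of 7 cases (median 0.47, adjusted p = 1.16e-05, adjusted p = 0.00157 with an estimated correlation) and mitochondrial ribosome genes in 19 of 72 (median 0.27, adjusted p = 3.4e-09). Meiosis genes had a median of 0.19 (adjusted p = 0.0113), glycolysis -0.42 (0.000701), translation factors -0.32 (0.00185), sulfur metabolism -0.32 (7.47e-05), trehalose and glycogen -0.31 (0.0113), heat shock genes -0.27 (0.0227), nitrogen catabolite repression -0.21 (0.044) and the phosphate regulon -0.19 (0.0191), while the stress response genes did not pass (0.364). Except for a cell markers, none of these passed with an estimated correlation, where sulfur metabolism had the lowest adjusted p (0.184). The turned array moved the counts of the other ages to 2683 at 12 generations, 3809 at 18-20 generations and 3191 for the trend. All 8-generation arrays and 18-20-generation array 7 belong to a set with other spot brightness than the other 20 arrays. With the set as a block, 337 genes passed at 8 generations and 157 at 1 generation, and that fit separates set from age only through 18-20-generation array 7. The 8-generation changes correlated with those at 12 generations at r = 0.0849 and with those at 18-20 generations at r = -0.0113 over genes, or 0.192 and 0.0703 with array 1 turned.

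At 12 generations, 2627 of 5865 genes changed (44.79%), 1364 upward and 1263 downward, and 318 rose and 275 fell by more than 2-fold. ADY2, an acetate transporter, rose 19.4-fold (log2 4.28 ± 0.338 SE, adjusted p = 2.42e-09, higher on 6 of 6 arrays), POT1, the thiolase of fatty acid oxidation, 18.8-fold (4.23 ± 0.367, 7 of 7), SPG1, a stationary phase gene, 17-fold (4.09 ± 0.398, 7 of 7), ADH2, the alcohol dehydrogenase that consumes ethanol, 12.9-fold (3.69 ± 0.365, 7 of 7), and POX1, the acyl-CoA oxidase, 10.5-fold (3.40 ± 0.348, 7 of 7), and these were the 5 largest rises. The 5 largest falls were RPS9A, a ribosomal protein (log2 -2.57 ± 0.196, adjusted p = 1.75e-10, 7 of 7), ANB1, the hypoxic form of translation factor eIF5A (-2.41 ± 0.208, 6 of 6), IZH4 (-2.21 ± 0.211, 7 of 7), CYB5, cytochrome b5 (-2.20 ± 0.275, 7 of 7), and TIR1, a cell wall mannoprotein (-2.09 ± 0.207, 7 of 7). Over all 27 arrays, the ADY2 probe was above background in both channels on 19 and the POX1 probe on 18, so their fold values are less certain. On array 3, ADY2 stood at 1.36 and TIR1 at -3.11, apart from the other arrays. CYB5 did not pass with the array set as a block (log2 -0.88, adjusted p = 0.0794, from 6.35e-11 upward over the other alternatives). All 12-generation arrays are in the same set, so that fit moves their values only through 18-20-generation array 7. It says nothing of a set effect on CYB5 at 12 generations.

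At 12 generations, ribosomal protein genes fell as a group. Of 99 measured, 71 fell and 28 did not pass (75 fell adjusted over the list alone), with a median of -0.88 (adjusted p = 5.57e-18, adjusted p = 0.1 with an estimated correlation). Of 78 ribosome biogenesis genes, 51 fell and 1 rose (median -0.69, adjusted p = 1.98e-12, adjusted p = 0.225 estimated), with NOP1, the methyltransferase of box C/D snoRNPs, at -1.79 ± 0.185. Subunits of RNA polymerases I and III fell in 17 of 20 cases (median -0.98, adjusted p = 5.01e-09, and adjusted p = 0.0454 with an estimated correlation), with RPA135 at -1.43 ± 0.174. Mitochondrial ribosome genes went the other way, 31 of 72 rising and 0 falling (median 0.30, adjusted p = 9.33e-05, adjusted p = 0.405 with an estimated correlation), with MRPL28 at 1.39 ± 0.139. The arrays differed widely for this list, with a mean of array medians of 0.37 ± 0.499 (SD, n = 7, from -0.39 to 1.02). Genes repressed by glucose rose in 16 of 21 cases (median 0.92, adjusted p = 2.59e-08, adjusted p = 0.1 estimated), with CYB2, the lactate dehydrogenase of mitochondria, at 2.95 ± 0.299 and SPG4 at 3.33 ± 0.218. Stress response genes rose in 37 of 59 cases (median 0.68, adjusted p = 2.07e-08, adjusted p = 0.231 estimated), with DDR2 at 2.64 ± 0.27. The vacuolar ATPase fell in 12 of 16 cases (median -0.54, adjusted p = 0.00066) and the retrograde response rose in 8 of 12 (median 0.83, adjusted p = 0.00222), both with an adjusted p of 0.0454 under an estimated correlation. Adjusted over the list alone, the counts at 12 generations differed from these by at most 1 gene for the other lists named. With the array set as a block, the median was -0.46 for ribosomal proteins, 1.27 for stress response genes and -0.34 for the vacuolar ATPase. These medians were moved only through 18-20-generation array 7, since all 12-generation arrays are in the same set. Without array 1 the median was 0.46 for the mitochondrial ribosome. In all, 28 of 46 lists passed with the preset correlation and 4 with an estimated one.

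At 18-20 generations, 3764 of 5865 genes changed (64.18%), 1932 upward and 1832 downward, and 734 rose and 815 fell by more than 2-fold. Among genes with a probe of their own and one sign on at least 6 of 7 arrays, the 10 largest rises were CYB2 (16.8-fold, log2 4.07 ± 0.299 SE, adjusted p = 5.63e-12), SPG4, a stationary phase gene (14.7-fold, 3.88 ± 0.235), CSR2 (10.1-fold, 3.33 ± 0.255), SUE1 (9.77-fold, 3.29 ± 0.295), the stress gene DDR2 (8.98-fold, 3.17 ± 0.27), IDP3, a peroxisomal isocitrate dehydrogenase (8.61-fold, 3.11 ± 0.253), POX1 (8.44-fold, 3.08 ± 0.348), CIT3, a mitochondrial citrate synthase (8.32-fold, 3.06 ± 0.309), NCE103, carbonic anhydrase (7.93-fold, 2.99 ± 0.351), and ALD3, an aldehyde dehydrogenase (7.7-fold, 2.95 ± 0.264). Each was higher on every array that measured it, 6 for SPG4 and 7 for the others. SPG1 (3.77 ± 0.612, on 3 arrays), CPP3 (3.40 ± 0.312, on 5) and MPC3 (3.40 ± 0.6, on 3) passed the threshold with larger values than CSR2 but were measured on fewer arrays. On array 7, NCE103 stood at 5.86, apart from the other arrays, which reached 2.82. Of the 10 largest falls by the same limit, 9 are given here. They were RPL22A, a ribosomal protein (log2 -3.54 ± 0.204, adjusted p = 1.33e-13), AAH1, adenine deaminase (-3.48 ± 0.188), RKI1, the ribose-5-phosphate isomerase (-3.06 ± 0.202), RPS9A (-3.04 ± 0.196), NIP7, a ribosome assembly factor (-3.04 ± 0.185), TRM11, a tRNA methyltransferase subunit (-2.97 ± 0.197), SAM2, the S-adenosylmethionine synthetase (-2.96 ± 0.194), RPL2A (-2.94 ± 0.246) and RPL18B (-2.92 ± 0.193). Each of these was lower on 7 of 7 arrays. RPL2A was at -5.37 on array 7, apart from the others. When arrays were scaled to each other, the 18-20-generation count was 2402 and log2 values were smaller, with CYB2 at 2.07 and RPL22A at -1.86.

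At 18-20 generations, all 99 ribosomal protein genes fell (median -2.01, adjusted p = 4.59e-30, adjusted p = 0.053 with an estimated correlation), and the mean of the array medians was -2.03 ± 0.439 (SD, n = 7). Of 78 ribosome biogenesis genes, 76 fell (median -1.57, adjusted p = 1.77e-21, adjusted p = 0.107 estimated), with NOP1 at -2.77 ± 0.185 and RRP5 at -2.68 ± 0.18. RNA polymerase I and III subunits fell in 19 of 20 cases (median -1.58, adjusted p = 5.63e-09, adjusted p = 0.053 estimated), with RPA135 at -2.73 ± 0.161. Of 31 translation factors, 27 fell and 1 rose (median -1.01, adjusted p = 1.8e-07, adjusted p = 0.126 estimated), with EFB1 at -2.76 ± 0.172 and TEF4 at -2.50 ± 0.166. Mitochondrial ribosome genes did not pass as a list (median 0.03, adjusted p = 0.537), with 21 rising and 13 falling of 72, among them MRPL28 at 1.45 ± 0.139 and RSM26 at -1.24 ± 0.249. Scaled to each other, the arrays gave a median of -1.04 for ribosomal proteins and -0.79 for ribosome biogenesis.

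**Figure D2:**
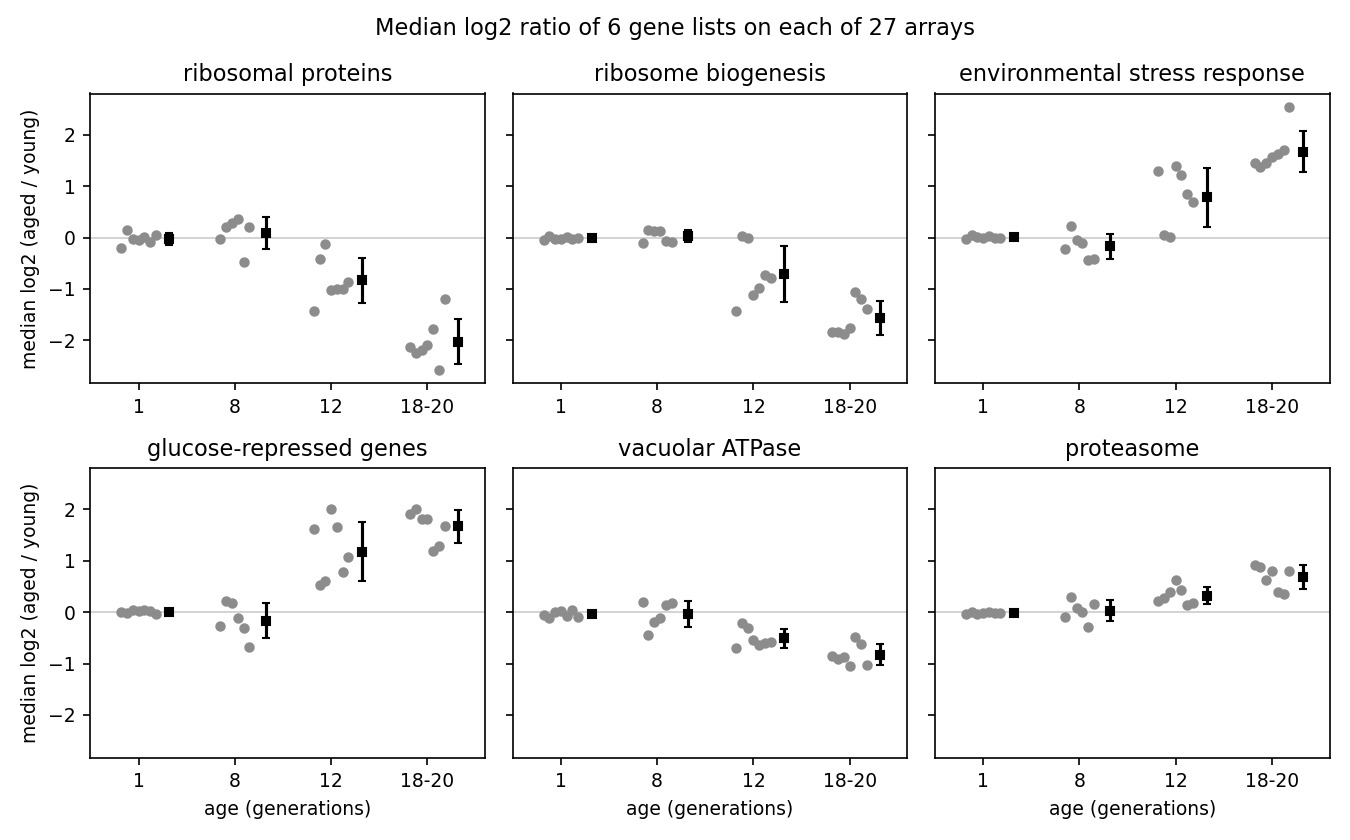
Median log2 ratio of aged over young (y axis) of 6 gene lists at each age in generations (x axis), with a grey point per array and a black square with bars for the mean and SD over the arrays of an age. Ribosomal protein medians lie between -2.58 and -1.19 at 18-20 generations and between -0.21 and 0.15 at 1 generation, and stress response medians between 1.38 and 2.55 at 18-20 generations.

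Genes of stress and of growth without glucose rose at 18-20 generations. Of 59 environmental stress response genes, 57 rose and 1 fell (median 1.75, adjusted p = 1.89e-15, adjusted p = 0.111 with an estimated correlation), with HSP12 at 2.87 ± 0.204 and the catalase CTT1 at 1.84 ± 0.28. Heat shock genes rose in 18 of 27 cases and fell in 6 (median 1.03, adjusted p = 0.0334, adjusted p = 0.337 estimated), with HSP42 at 2.48 ± 0.286, HSP26 at 1.91 ± 0.334 (1.18 on arrays 1 to 4 alone) and the ribosome-bound chaperone SSB2 at -1.99 ± 0.177. This list did not pass without array 7 (adjusted p = 0.0665) or on arrays 1 to 4 alone (adjusted p = 0.109, with a range of 0.00821 to 0.337 over the alternatives), and HSP12 on array 7 stood apart at 3.90. Glucose-repressed genes rose in 19 of 21 cases (median 1.66, adjusted p = 9.67e-08, adjusted p = 0.107 estimated), among them the hexokinase HXK1 at 2.90 ± 0.214. Gluconeogenesis and glyoxylate genes rose in 14 of 16 cases and fell in 2 (median 1.68, adjusted p = 0.00354, adjusted p = 0.239 estimated), with JEN1, the lactate transporter, at 2.56 ± 0.279 and ACS1 at 2.39 ± 0.333. On arrays 5 to 7 alone, this median was 0.73 and JEN1 stood at 1.66. PCK1 stood at 1.67 ± 0.332 (adjusted p = 8.55e-05) and at 0.62 on arrays 5 to 7 alone (adjusted p = 0.281, and from 3.77e-12 upward elsewhere). Fatty acid oxidation genes rose in 25 of 32 cases (median 1.03, adjusted p = 3.09e-06, adjusted p = 0.126 estimated), tricarboxylic acid cycle genes in 16 of 22 (median 0.72, adjusted p = 0.000242, adjusted p = 0.102 estimated), and oxidative phosphorylation genes in 21 of 39 (median 0.50, adjusted p = 0.00933, adjusted p = 0.461 estimated). Oxidative phosphorylation genes did not pass on arrays 5 to 7 alone (median 0.25, adjusted p = 0.169) or with the array set as a block (0.35, adjusted p = 0.114), and their adjusted p ran from 0.00247 upward elsewhere. CIT1, mitochondrial citrate synthase, was at 2.28 ± 0.112. The retrograde response, the transcription that answers to mitochondrial dysfunction, rose in 7 of 12 cases (median 0.75, adjusted p = 0.0205, adjusted p = 0.0896 estimated), with CIT2 at 1.68 ± 0.426 on 3 arrays. This list did not pass on arrays 1 to 4 alone (median 0.23, adjusted p = 0.153, and from 0.00634 upward elsewhere). DLD3 of the same list fell to -1.02 ± 0.265, was lower on 4 of 7 arrays, and stood at 0.45 on arrays 5 to 7 alone (adjusted p = 0.0324, with a range of 2.18e-12 to 0.387 over the alternatives). ADH1, the alcohol dehydrogenase that makes ethanol, was at -0.74 ± 0.212 (adjusted p = 0.00349, lower on 6 of 7 arrays). It did not pass when arrays were scaled to each other, alike arrays averaged or the array set used as a block (adjusted p = 0.0987, 0.0668 and 0.215, and from 0.000391 upward elsewhere).

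Genes of protein breakdown and reserve storage rose as well. Trehalose and glycogen genes rose in 18 of 20 cases (median 1.499, adjusted p = 8.52e-07, adjusted p = 0.107 with an estimated correlation), with the glycogen synthase GSY2 at 2.22 ± 0.219. Proteasome genes rose in 31 of 36 cases (median 0.77, adjusted p = 2.85e-06, adjusted p = 0.107 estimated), with the transcription factor RPN4 at 2.33 ± 0.245. Vacuolar proteases and autophagy genes rose in 18 of 25 cases (median 0.64, adjusted p = 0.000465, adjusted p = 0.107 estimated), with ATG8 at 2.75 ± 0.228 and PRB1 at 2.31 ± 0.186. Stationary phase genes rose in 12 of 15 cases (median 1.83, adjusted p = 0.000205, adjusted p = 0.111 estimated). Meiosis genes rose in 16 of 33 cases (median 0.35, adjusted p = 0.00161, adjusted p = 0.255 estimated), with IME1 at 2.62 ± 0.437, which stood at 1.10 on arrays 5 to 7 alone (adjusted p = 0.125, and from 8.87e-13 upward elsewhere). Oxidative stress genes rose in 17 of 28 cases (median 0.69, adjusted p = 0.0205, adjusted p = 0.126 estimated, 0.42 and adjusted p = 0.089 on arrays 5 to 7 alone, and from 0.00692 upward elsewhere), DNA repair genes in 22 of 44 (median 0.34, adjusted p = 0.0313, adjusted p = 0.189 estimated, adjusted p = 0.0691 without array 7 and 0.186 on arrays 1 to 4 alone, range 0.00443 to 0.189 over the alternatives) and hexose transport genes in 10 of 15 (median 0.70, adjusted p = 0.0334, adjusted p = 0.404 estimated, adjusted p = 0.0645, 0.0599 and 0.0542 without array 1, 2 or 4, range 0.00275 to 0.65). The hexose transport list did not pass either with bright probes alone (adjusted p = 0.0742), alike arrays averaged (0.139), the array set as a block (0.157) or arrays 5 to 7 alone (0.65). RNR3, a DNA damage marker, was at 0.32 ± 0.177 (adjusted p = 0.115), at 0.45 without array 5 (adjusted p = 0.038) and at 0.35 without 12-generation array 1 (adjusted p = 0.0482). It passed as well without background correction, with array weights and with spots that were not found kept, and stood furthest from passing on arrays 5 to 7 alone (adjusted p = 0.592). Its probe was above background in both channels on 9 of the 27 arrays, so these values rest on weak signal.

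Phosphate regulon genes fell at 18-20 generations in 14 of 18 cases (median -1.39, adjusted p = 0.000122, adjusted p = 0.0896 with an estimated correlation), with PHO84, the phosphate transporter, at -2.49 ± 0.185. Amino acid biosynthesis genes fell in 34 of 50 cases (median -0.97, adjusted p = 4.13e-06, adjusted p = 0.128 estimated), with HIS1 at -2.58 ± 0.19. This median was -1.48 on arrays 1 to 4 alone and -0.45 on arrays 5 to 7 alone. Sterol genes fell in 20 of 26 (median -0.97, adjusted p = 0.000447, adjusted p = 0.126 estimated), with ERG2 at -2.69 ± 0.254. Sterol genes did not pass on arrays 5 to 7 alone (median -0.43, adjusted p = 0.0809, and from 4.41e-06 upward elsewhere). Phospholipid and fatty acid genes fell in 13 of 24 (median -0.52, adjusted p = 0.00383, adjusted p = 0.107 estimated), with HNM1, the choline transporter, at -2.55 ± 0.173. Sulfur metabolism genes fell in 16 of 27 (median -0.42, adjusted p = 0.021, adjusted p = 0.331 estimated), with SAM1 at -2.65 ± 0.168. Sulfur metabolism did not pass on arrays 5 to 7 alone (median -0.15, adjusted p = 0.234), with alike arrays averaged (-0.27, 0.0749) or with the array set as a block (-0.25, 0.222), and its adjusted p ran from 0.00275 upward elsewhere. Vacuolar ATPase genes fell in 13 of 16 (median -0.77, adjusted p = 0.000668, adjusted p = 0.053 estimated), with VMA3 at -1.58 ± 0.168. Adjusted over the list alone, 18 tricarboxylic acid cycle genes, 19 trehalose and glycogen genes and 8 retrograde response genes rose and 10 mitochondrial ribosome genes fell, and the counts of the other lists described at this age were as given. With an estimated correlation, 0 of the 28 lists that passed at 18-20 generations kept an adjusted p under 0.05.

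DSE2, a cell separation gene, fell at 18-20 generations (log2 -2.29 ± 0.179, lower on 7 of 7 arrays). CTS1, the chitinase, stood at -0.69 ± 0.222 (adjusted p = 0.00826), and at 0.22 with the array set as a block (adjusted p = 0.388, with a range of 2.87e-09 to 0.683 over the alternatives). It was at -1.03 without array 7 and did not pass on arrays 5 to 7 alone (-0.18) or with alike arrays averaged (-0.19). Markers of alpha cells fell in 5 of 5 cases (median -1.78, adjusted p = 0.00564, adjusted p = 0.0777 with an estimated correlation), with MF(ALPHA)2 at -2.54 ± 0.199, MF(ALPHA)1 at -1.88 ± 0.229 and STE3 at -1.78 ± 0.126, and SAG1 at -0.64 ± 0.193. MFA1 of the a cells rose by log2 0.56 ± 0.149, while a cell markers did not pass as a list (adjusted p = 0.0797). When arrays were scaled to each other, neither SAG1 (-0.35, adjusted p = 0.162) nor MFA1 (0.27, adjusted p = 0.151) passed, nor on arrays 1 to 4 alone (-0.33, adjusted p = 0.258, and 0.43, adjusted p = 0.062). Elsewhere their adjusted p ran from 2.14e-05 and 0.000389 upward. The labels do not settle the mating type of the cells. The series description can be read as naming the a type, in which alpha cell genes are not transcribed. The MF(ALPHA)1, STE3, SAG1 and AFB1 probes were above background in both channels on all 27 arrays, and that of MF(ALPHA)2 on 26. Probes of a cell markers were so on 10 arrays (STE6) to 20 (STE2), with MFA1 on 13. Probes of meiosis and sporulation genes passed this limit too (DIT1 on 25 arrays, DMC1 on 20 and SPO20 on 19). Passing it does not by itself show that a gene is transcribed. The dim a cell probes beside the alpha cell probes go against cells of the a type alone but do not settle the type. Silencing and rDNA genes did not pass as a list (adjusted p = 0.795), with 8 rising and 10 falling of 31. SIR2 changed by -0.31 ± 0.107 (adjusted p = 0.0137) and FOB1 by -0.43 ± 0.161 (adjusted p = 0.0201), and neither passed when arrays were scaled to each other (adjusted p = 0.322 and 0.168) or alike arrays averaged (0.0625 and 0.227). SIR2 did not pass on arrays 1 to 4 alone (adjusted p = 0.245) or with array weights (0.0608), and ran from 0.00704 upward elsewhere. FOB1 did not pass on arrays 5 to 7 alone (0.378), with the array set as a block (0.313) or without array 3 (0.0649), and ran from 1.62e-05 upward elsewhere. Histone genes did not pass either (adjusted p = 0.795), with HTA1 at -0.07 ± 0.172 (-0.46 with median centring, where it passed). Of 9 measured, 2 rose and 1 fell, and these calls did not hold throughout. HTB1 was at 0.85 ± 0.268 on 3 arrays, at 0.48 without array 5 (adjusted p = 0.165) and at 0.13 with median centring (adjusted p = 0.732, and from 0.000727 upward elsewhere). HHO1 was at 0.47 ± 0.115 and at 0.19 on arrays 5 to 7 alone (adjusted p = 0.374, from 3.69e-08 upward elsewhere), and HTA2 at -0.89 ± 0.196 and at -0.46 with the array set as a block (adjusted p = 0.14, from 1.1e-08 upward elsewhere).

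The changes at 12 and at 18-20 generations shared most of their genes. Of the genes that rose, 1162 rose at both ages where 449.3 are given by independent lists, and of the genes that fell, 1090 where 394.5 are given, while 23 changed in opposite directions. The log2 changes correlated at r = 0.848 over genes (0.0442 for simulated unchanged ages in the same fit), with a covariance of 0.505 (0.0015 simulated). The 18-20-generation changes differed from those at 12 generations for 1156 genes in limma, 500 of them higher and 656 lower at 18-20 generations. The 12-generation array 1 correlated at r = 0.853 to 0.879 over genes with 18-20-generation arrays 1 to 4 and at 0.226 to 0.726 with the other 12-generation arrays, which correlated at 0.238 to 0.784 with those older arrays. The labels do not say whether it shares RNA with them. Without it, 1025 genes rose at both ages (419.7 by independent lists), 978 fell (378.1) and 62 changed in opposite directions, with r = 0.785 and a covariance of 0.457, and 1610 genes differed between the ages, 756 higher and 854 lower at 18-20 generations.

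**Figure D3:**
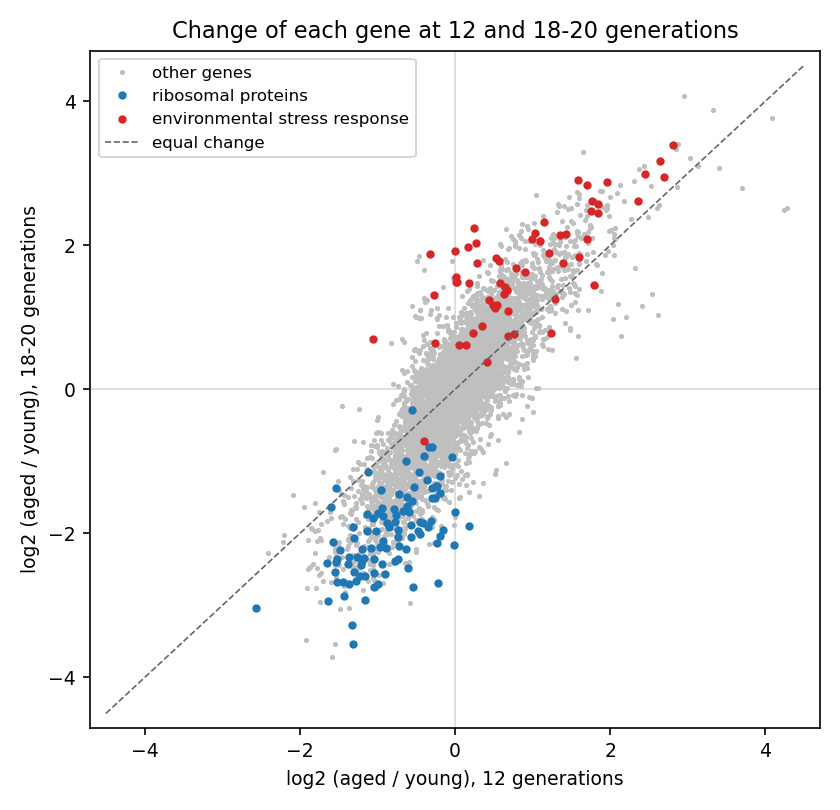
Log2 ratio of aged over young at 12 generations (x axis) and at 18-20 generations (y axis), a point per gene, with ribosomal proteins in blue, stress response genes in red and a dashed line where both are equal. Ribosomal proteins lie below 0 at 18-20 generations and mostly below the line, with a median of -2.01 against -0.88 at 12 generations.

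Against the 1-generation arrays in place of 0, 8 generations showed 0 genes past the threshold in limma (257 at an unadjusted p under 0.05, lowest p BAR1, IBD2 and IRC18), 12 generations 1601 (835 up and 766 down) and 18-20 generations 3034 (1551 up and 1483 down). With 8-generation array 1 turned, 2 genes passed for 8 generations. SPG4 rose by log2 3.56 ± 0.315 at 12 generations and 4.12 ± 0.327 at 18-20, and CYB2 rose by 3.97 ± 0.431 at 18-20. CPP3 (3.55 ± 0.416) and MPC3 (3.53 ± 0.725, on 3 arrays) were among the 5 largest rises at 18-20 generations, and NIP7 (-3.18 ± 0.27) and RKI1 (-3.14 ± 0.291) among the 5 largest falls. SND3 differed by -2.13 ± 0.4 at 12 generations, where 1 generation stood at 1.32. With array weights, 210 genes passed for 8 generations and 2531 for 12 generations, and when arrays were scaled to each other 18-20 generations gave 1762.

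Over all 27 arrays, 3202 of 5865 genes had a slope with generation past the threshold, 1629 upward and 1573 downward. The 5 steepest rises were SPG1 (log2 0.28 ± 0.0504 per generation), SPG4 (0.26 ± 0.0273), CYB2 (0.25 ± 0.0321), ADY2 (0.23 ± 0.0557) and POT1 (0.23 ± 0.0558), and 4 of the 5 steepest falls were AAH1 (-0.21 ± 0.0206), RPL22A (-0.20 ± 0.0217), RKI1 (-0.19 ± 0.0214) and RPS9A (-0.19 ± 0.0211). A slope need not stand for a steady rise. ADY2, POT1 and SPG1 stood lower at 18-20 generations (2.52, 2.49 and 3.77) than at 12 (4.28, 4.23 and 4.09). Of these differences, that of ADY2 alone passed in limma (adjusted p = 0.0381). SPG4 and CYB2 stood higher at 18-20 generations. Ribosomal protein genes fell in 98 of 99 cases, with a median slope of -0.12 (adjusted p = 8.69e-28, adjusted p = 0.162 with an estimated correlation). Stress response genes rose in 54 of 59 cases with a median slope of 0.10 (adjusted p = 3.68e-14, adjusted p = 0.162 with an estimated correlation). Without the 1-generation arrays, ADY2 and POT1 did not pass (slopes of 0.25 and 0.21, adjusted p = 0.111 and 0.175, and from 3.17e-06 and 1.09e-06 upward elsewhere). When arrays were scaled to each other, 2069 genes had a slope past the threshold.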

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

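All tests of explanations in this part were set down only after the results they concern had been seen. Values on single arrays were examined for 136 groups of values of 1 age, and an array stood apart from its group in 12 of them (Dixon's test), where chance gives about 1 in 20.

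At 12 generations, array 3 stood apart for ADY2 at 1.36, next to 4.34 on the nearest array, and for TIR1 at -3.11, next to -2.18. Array 1 stood apart for amino acid biosynthesis genes (median -1.10, nearest -0.61), sterol genes (-1.31, nearest -0.60) and phospholipid and fatty acid genes (-0.83, nearest -0.30). At 18-20 generations, array 7 was the array that stood apart each time. It was at 5.86 for NCE103 (nearest 2.82), -5.37 for RPL2A (nearest -3.14), 3.90 for HSP12 (nearest 2.93) and 1.39 for CTS1, where the others lay between -1.27 and -0.80. Its list medians were 2.41 for trehalose and glycogen genes (nearest 1.39), 2.55 for stress response genes (nearest 1.70) and 0.77 for DNA repair genes (nearest 0.33). Array 7 is the array of this age that belongs to the set of other spot brightness. Without it, which leaves the arrays of the larger set, 3597 genes changed at 18-20 generations, against 3764 with it.

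Changes differed between 12 and 18-20 generations for 1156 genes, tested as the difference itself. Among gene lists past the threshold at 12 or 18-20 generations, the difference of 18-20 minus 12 had a median of -1.15 for ribosomal proteins (adjusted p = 2.45e-32), -0.93 for ribosome biogenesis (1.7e-21), -0.67 for RNA polymerases I and III (1.66e-05), -0.34 for translation factors (0.00116), -0.30 for the mitochondrial ribosome (0.00613), -0.71 for the phosphate regulon (0.00116), -0.53 for amino acid biosynthesis (0.000175) and -0.29 for phospholipid and fatty acid genes (0.0156). It had a median of 0.92 for trehalose and glycogen (4.95e-09), 0.73 for stress response genes (2.47e-13), 0.52 for the tricarboxylic acid cycle (7.9e-05), 0.48 for glucose-repressed genes (0.00218), 0.40 for the proteasome (3.94e-05), 0.38 for oxidative phosphorylation (0.00157) and 0.33 for vacuolar proteases and autophagy (0.00116). With an estimated correlation, the adjusted p of these lists ran from 0.141 to 0.694. Without 12-generation array 1, which correlated at 0.853 to 0.879 over genes with 18-20-generation arrays 1 to 4, 1610 genes differed, the median difference of ribosomal proteins was -1.26 (adjusted p = 1.25e-28), and alpha cell markers passed too (-0.84, adjusted p = 0.0447, against 0.0505 with it). Of the 27 genes named at either age, 10 differed. Each of the 10 was named at 1 of the ages for its size there and was further from 0 at that age. The choice itself favours such differences, so this count does not bear on how common they are. RPS9A and POX1, named at both ages, did not differ (adjusted p = 0.241 and 0.696 in limma). ADY2 was lower at 18-20 generations by a difference of -1.76 (adjusted p = 0.0381), measured on 3 of the 7 arrays of that age, and SUE1 higher by 1.64 (0.00729). RPL22A differed by -2.22 (1.47e-05), AAH1 by -1.55 (0.000235), RKI1 by -1.57 (0.000404), NIP7 by -1.67 (0.00013), TRM11 by -2.39 (7.43e-06), SAM2 by -1.21 (0.00271), RPL2A by -1.30 (0.00946) and RPL18B by -1.76 (0.000106), each further down at 18-20 generations.

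The fall of ribosomal protein genes at 18-20 generations may have technical sources, and 3 were tested. If it came from 1 extract measured on the much alike arrays 1 to 4, it would be missing on arrays 5 to 7, but the highest ribosomal protein median on these was -1.19. If it came from dye bias, it would be absent in one dye orientation, but the mean median was -1.82 on the 4 arrays with aged cells in Cy5 and -2.31 on the 3 with aged cells in Cy3. If it came from probe brightness, random lists of equally bright probes would fall as far, but their lowest median in 10000 draws was -0.446, a share of 1e-04, the smallest the draws can give. A change of growth rate or nutrient state with age stays open beside age itself, as do effects of sorting, and no biological explanation was tested.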

How the results depend on the processing

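The alternatives on 8-generation array 1, alike arrays, array set and part of the 18-20-generation arrays were chosen after seeing the data. The counts of 12 and 18-20 generations, of 18-20 minus 1 generation and of the trend kept within 1.5 times under the other alternatives run, except where arrays were scaled to each other. The cause of the changes below was not tested unless stated.

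Scaling between arrays gave 67 genes at 1 generation, 4 at 8 generations, 2402 at 18-20 generations, 1 for 8 minus 1 generation, 1762 for 18-20 minus 1 and 2069 for the trend. It gives arrays of all ages an equal spread, which widens the 1-generation ratios by its construction. Array weights gave 2 genes at 1 generation, 755 at 8 generations, 210 for 8 minus 1 and 2531 for 12 minus 1. Print-tip loess gave 1 gene at 8 generations. With 8-generation array 1 turned, 532 genes changed at 8 generations and 2 for 8 minus 1. Averaging alike arrays gave 1 gene at 1 generation, with 2088 at 12 and 2922 at 18-20 generations. The array set as a block gave 157 genes at 1 generation, 337 at 8 generations and 308 for 8 minus 1, all of which rest on 18-20-generation array 7, the array outside 8 generations in its set, and 2002 at 12 and 3504 at 18-20 generations. The count at 12 generations rests on that array too, since none of the 12-generation arrays is in its set. On arrays 5 to 7 alone, 2922 genes changed at 18-20 generations, and on arrays 1 to 4 alone 3549.

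The replicate block gave 9 genes at 8 generations. Replicate numbers did not pair the arrays. Of 39 same-numbered pairs of different ages, 14 had a correlation above 0.1 (range -0.394 to 0.292), and 4 of 27 arrays lay closest to their own number. The block moved no other count by over 1.5 times.

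The count of lists past the threshold at 1 generation, 2, became 8 with median centring and 1 without background correction, with scaling, without the dye term, with the authors' table and with either part of the 18-20-generation arrays. It was 1 with bright probes alone as well, where a cell markers could not be tested. The tests of lists do not use array weights or the variance prior, so those settings do not bear on their p. With an estimated correlation it was 0 at 1 generation, 1 at 8, 4 at 12, 0 at 18-20 and 0 for the trend.

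Leaving out each array in turn gave 0 genes at 1 generation, 0 to 395 at 8 generations (395 without 8-generation array 1), 2327 to 2801 at 12, 3573 to 3874 at 18-20, 0 to 2 for 8 minus 1, 1276 to 1757 for 12 minus 1, 2829 to 3191 for 18-20 minus 1 and 3023 to 3270 for the trend. Lists past the threshold ranged from 1 to 5 at 1 generation (5 without 12-generation array 3), 3 to 10 at 8 (3 without 8-generation array 6), 27 to 29 at 12, 27 to 29 at 18-20 and 26 to 28 for the trend.

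Directions turned for a cell markers at 1 generation (0.0378 with scaling and 0.0314 without the dye term), CTS1 at 18-20 generations (0.223 with the set as a block), DLD3 (0.449 on arrays 5 to 7 alone) and the median of heat shock genes at 8 generations (-0.2285 to 0.00418 over the arrays left out, turned without 8-generation array 5). A scan or slide block was not run, since the files give no such batch. Signal over background limits red most, with 61.76% of spots above it on the array with the fewest.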

Other observations

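All tests of explanations in this part, the counts of other splits included, were set down only after the results they concern had been seen.

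Of all 5865 genes, 1932 rose and 1832 fell at 18-20 generations. Among the lists that did not pass there, 5 more with members in both directions are described here. In the iron regulon, 12 of 30 genes rose and 8 fell (adjusted p = 0.346), led by the biotin synthesis genes BIO4 at 2.73 ± 0.238 (SE) and BIO3 at 1.75 ± 0.169, the heme oxygenase HMX1 at 2.51 ± 0.18 and the iron-sulfur scaffold ISU1 at 2.01 ± 0.186. The biotin transporter VHT1 was at -0.86 ± 0.136. Among actin and polarity genes, 12 of 35 rose and 5 fell (adjusted p = 0.122), with ABP1 at 1.66 ± 0.137 and SAC6 at 1.40 ± 0.127. Among subtelomeric families, 10 of 19 rose and 4 fell (adjusted p = 0.115), with PAU23 at 2.11 ± 0.156 and DAN1 at -2.09 ± 0.282, which stood at -0.43 on arrays 5 to 7 alone (adjusted p = 0.55, from 8.94e-14 upward elsewhere) and whose probe was above background in both channels on 15 of 27 arrays. Of 38 G1 and S phase genes, 19 fell and 4 rose (adjusted p = 0.0515), with TOS6 at -1.52 ± 0.135 and GIC2 at 1.38 ± 0.13. Among nitrogen catabolite repression genes, GDH2 rose to 2.19 ± 0.143 and MEP2 fell to -1.71 ± 0.301, with 10 of 27 rising and 7 falling (adjusted p = 0.713).

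The remaining lists at 18-20 generations did not pass. These were glycolysis (adjusted p = 0.505), fermentation (0.919), a cell markers (0.0797), G2 and M phase genes (0.505), MCM and M-G1 genes (0.647), haploid-specific and pheromone response genes (0.874), biotin synthesis and uptake (0.707), cell wall (0.874), unfolded protein response (0.0935) and septins and cytokinesis (0.422).

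Whether chance arrangements of the arrays give counts as large was examined for each comparison. At 12 generations, 1 of 64 ways of turning the arrays gave as many genes as the real 2627 (highest other 1980), and at 18-20 generations 1 of 64 gave as many as 3764 (highest other 3145). This excludes chance only if each array is independent. With much alike arrays turned together, 1 of 16 ways gave as many at 12 generations (highest other 1980) and 1 of 4 at 18-20 generations (highest other 2497), too few ways for a share under 0.05. For 12 minus 1 generation, 1 of 100 splits gave 1601 or more (highest other 997), and 1 of 100 with alike arrays kept together (highest other 1140). For 18-20 minus 1 generation, 1 of 100 gave 3034 or more (highest other 1096), and 1 of 64 with alike arrays kept together (highest other 1451). For the trend, 1 of 100 reassignments of ages gave 3202 or more (highest other 5), and 1 of 100 with alike arrays kept together (highest other 2087). Arrays were kept together only within an age, and 12-generation array 1 is as much alike to 18-20-generation arrays 1 to 4. Without it, 1 of 100 reassignments gave the real 3149 or more (highest other 2044). This excludes chance for these 3 comparisons only if the arrays that were not kept together are independent, which the labels do not settle. For 1 generation, 8 generations and 8 minus 1 generation the real count was 0, which every arrangement reaches by construction (64 of 64, 32 of 32 and 100 of 100), so these counts do not bear on chance. The highest other counts were 0 at 1 generation, 1 for 8 minus 1 generation and 532 at 8 generations, with array 1 turned, which points to a structure of these arrays.

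The 8-generation array 1 ran against arrays 2, 3 and 4. A dye effect left after normalization would make arrays of one orientation alike, but the highest r with arrays 2 and 3, of the same orientation, was -0.58. An exchange of its 2 channels may account for it, since the lowest r with the 14 older arrays was 0.144 once the array was turned. With the same older arrays, 8-generation arrays 2, 3 and 4 correlated at -0.101 to 0.289 and arrays 5 and 6 at -0.176 to 0.251. An r with older arrays therefore does not settle the direction of an array of this age. Its values matched the authors' processed values of array 3 at r = 0.943, as after an exchange of the files of replicates 1 and 3 in the scanner files or in the table. Such an exchange turns no sign if both arrays were inverted, as their titles and channel labels give, and the description of array 3 does not give the inversion, so this explanation cannot be told apart from others here. The design gives no biological explanation, and none was tested.

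Alpha cell markers fell at 18-20 generations. Random lists of equally bright probes had a median as low as its -1.78 in a share of 0.0143 of 10000 draws, and the lowest reached -2.75. The list was taken from 46 after its fall was seen, and the share is not adjusted for that choice. It therefore argues only weakly against probe brightness. If both mating type cassettes had become expressed, as after loss of silencing, genes that diploid cells repress would fall together. Of 10 measured, chosen after the fall was seen, 5 fell, among them STE4 at -1.18 ± 0.125, HO at -1.28 ± 0.161 and FAR1 at -1.71 ± 0.2, and 5 did not pass, among them RME1 at 0.26 ± 0.117 and NEJ1 at -0.01 ± 0.143, whose probe was above background in both channels on 7 of 27 arrays. Of the cassettes' own probes, which each match more than 1 cassette, both of alpha 1 fell (-1.07 ± 0.185 and -0.97 ± 0.153, adjusted p = 1.19e-05 and 3.64e-06), as in diploid cells, and those of alpha 2 and a2 rose (1.62 ± 0.161, 1.58 ± 0.157 and 1.37 ± 0.219). The a1 probe, whose gene this explanation needs expressed, had too few unmarked spots to be tested, and was above background in both channels on 3 of 27 arrays and in the aged channel on 8. Of all 5865 genes, 1832 fell at this age, so 5 falls of 10 say little. The list of haploid-specific and pheromone response genes, which shares members with these 10, did not pass (mean of array medians 0.12). Markers of a cells, which alpha 2 represses, did not fall (0.40 ± 0.164 SD, from 0.13 to 0.63), though their probes are dim. In cells of the alpha type, alpha 2 would repress them already, so the lack of a fall would not bear on this explanation. The falls of alpha 1 and of the 5 genes go with this explanation. The 5 genes that did not pass go against it, as does the haploid-specific list, which is not separate from the 10 genes. It cannot be told apart from others here. The meaning of the fall depends on the mating type of the cells, which the labels do not settle. The dim a marker probes beside the alpha marker probes go against the a type alone but do not settle it either. A change in growth state with age stays open and was not tested.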
